A study of Sus scrofa with 8 samples.

How the data were processed

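RNA from the colon of 8 pigs, 4 on a control diet and 4 on a diet with pea fiber, was measured on one-colour arrays, 1 pig per array. Per the labels' protocols, total RNA was extracted with Trizol from frozen tissue, and Cy3-labelled cRNA was made from 0.5 ug of it by linear amplification. Per the file headers, the scanned images were read with Agilent Feature Extraction 10.7.3.1, which subtracted background and detrended each array. The deposited scanner files give each spot's processed signal as an intensity on a linear scale, not normalized between arrays, with the median spot and local background intensity and flags for spots well above background, saturated or non-uniform. The authors also deposited a normalized table and a series matrix of log2 values. Their 43661 shared probes were identical and each array had a median of 5.47. Against the scanner files, they kept the order of the processed signal within each array and had the same distribution on all arrays, as quantile normalization gives, with no centring of genes and no change of direction. How the authors made them is not given in the sources used here. Which part of the colon was taken, and whether the tissue was full thickness or mucosa, is not given in the labels.

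Each array held 45220 features, of which 43803 were spots for transcripts, for 43603 probes. Between 28646 and 31297 spots per array were well above background, and 0 were saturated. The 75th percentile of the processed signal was 286.0 to 345.9 on slide 1 and 381.7 to 399.0 on slide 2, with a median local background of 27.0 to 28.0 and 34.0 to 35.0. Each slide was scanned as 1 set and held 2 pigs of each diet, so slide and scan cannot be told apart, while diet and slide are balanced. With the number of arrays as the limit, the sensitivity was taken from simulated data with the spread of these arrays and 200 changed probes among 30282. There limma recovered 0.0% of probes changed 1.5-fold, 35.0% of those changed 2-fold and 82.5% of those changed 4-fold. The simulated probes were independent of each other and held no slide structure. Their spread came from a fit without the slide, so it counts the slide differences as noise. The shares recovered therefore apply to that fit and not to the fit with the slide as a block.

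The processed signal was put on a log2 scale and each array's 75th percentile over the non-control spots was subtracted. Spots of one probe were averaged, leaving out flagged spots where another spot of the probe remained. Probes well above background on at least 4 of the 8 arrays were tested, a filter that does not use the diet. The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are pea fiber minus control on the log2 scale, and errors marked SE come from limma for genes and from a linear model of the scores for list scores. The p-values of single genes and of permutations measure the spread between pigs. They take the pigs as independent, since the labels do not give the pen of each pig. Camera's p-values compare the genes of a list with all other genes. With the preset correlation they take these genes as nearly independent, so they do not measure the spread between pigs. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

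Probes were named through their Entrez gene identifier for 13297 probes, through an accession for 1176 and by the symbol in the deposited table for 944, while 28186 of 43603 probes had no symbol and stayed unnamed. The named probes covered 7474 symbols, and 1004 probes carried a placeholder symbol. Symbols on an array can be old. Where a gene had several tested probes, the one with the highest mean signal over all arrays stood for it, which gave 6182 genes, and the number of probes with the same direction is given where it matters.

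Gene lists for barrier, mucus, fermentation, immune, metabolic, proliferation and stress genes and for the cell types that a piece of colon can hold were fixed before the data were examined, 31 lists with 965 entries, of which 630 matched a named probe. The 28 lists with at least 5 tested genes were tested with camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and the exact permutation test of a list score used the 35 splits of the 8 pigs. The lists for mast cells and eosinophils, with 4 tested genes, for red blood cells, with 2, and for sex-linked genes, with 1, were not tested. In simulations of the 28 lists over 6182 genes with no effect and the correlations estimated here, camera with the preset correlation called 5.76 lists on average in 50 runs, and with an estimated correlation 0.00. This simulation replaced a first version with a correlation of 0.3 in every list, which rerun here gave 8.82 and 0.06 lists. In runs without correlation, camera with the preset correlation called a list shifted by −0.5 in 100.0% of runs. The other list tests were not run on a shifted list. The genes named were fixed by rule before the data were examined: the 10 on each side that passed the threshold with the diets apart and the largest change, filled up with those of smallest unadjusted p where fewer passed (here all 20), the 2 members of each list with the smallest p or 4 where the list passed camera, and a fixed set of barrier, immune and fermentation genes. Of the genes this rule names, 3 are not reported here.

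Alternatives fixed before the data were examined were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization or median centring of the processed signal, the authors' table, no filter and a filter on all 8 arrays, the slide as a block, each slide alone, eBayes with trend and robust, array quality weights, each pig left out in turn, flagged spots kept, an adjusted threshold of 0.10, a Welch test per probe, a 1.5-fold rule, camera with an estimated correlation, fry, and the mean of all probes of a gene. The normexp correction used the median spot signal, since the scanner files analysed here hold no mean spot signal, and this was decided after the files were seen. Added after the data were seen were the level of the Y-linked gene UTY as a covariate, alone and with the slide as a block, the slide block together with an estimated correlation, and the exact permutation of list scores. A fit without control 3 and pea fiber 4 together was run and left out, since these pigs had been picked by their values.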

Results

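The colon of pigs raised on a diet with pea fiber was compared with that of pigs on a control diet. Weaned crossbred pigs, 50 in all, were assigned at random to the diets from 28 days of age, in 5 pens of 5 pigs per diet. The fibrous diet held 10 to 20% pea fiber, a plant cell wall material that colonic bacteria ferment in part to short-chain fatty acids. At day 160, which the labels give both as age and as days after weaning, 4 pigs per diet were slaughtered and RNA from pieces of colon was hybridised, 1 pig per array, to one-colour Agilent pig arrays. The comparison asks which colonic transcripts differ after long intake of pea fiber. Each array held 43603 probes for transcripts, and 69.6% ± 1.54 (SD, n = 4) of the spots were well above background in control samples against 68.6% ± 2.75 (SD, n = 4) in pea fiber samples. The number of arrays limits the precision of every value below. Pigs are named by their diet and the number in their label.

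Genes of the interferon response, the antiviral program that interferons switch on, had lower means in the colon of pea fiber pigs. All 27 tested members were lower in mean, by 0.67 on average on the log2 scale (pea fiber minus control −0.67, a fold of 1.60). MX1, an antiviral GTPase, was at a log2 signal of 4.92 ± 0.68 (SD, n = 4) in controls and 3.49 ± 0.22 (SD, n = 4) in pea fiber pigs. The difference was −1.43 ± 0.32 (SE), with the same direction in 5 of 5 probes. HERC5, the ligase that attaches ISG15 to proteins, differed by −1.09 ± 0.19 (SE), IFI44 by −0.86 ± 0.24 (SE) and DHX58, an RNA sensor, by −0.81 ± 0.23 (SE). In each of these 4 genes every pea fiber pig lay below every control. Adjusted over the list alone, these 4 genes passed limma's test, with HERC5 at an adjusted p of 0.00867. With 1 pig left out HERC5 stayed between 0.00836 and 0.036 on this scale, and on slide 2 alone it was at 0.122. MX1 was at 0.0515 without control 3, 0.0601 without pea fiber 6, 0.0526 without pea fiber 8 and 0.0673 without pea fiber 10. DHX58 and IFI44 missed the threshold without control 3 (0.052 for both) and without any 1 of the pea fiber pigs, with values of up to 0.109 without pea fiber 6. Over all genes 0 members passed in limma, and 11 had an unadjusted limma p under 0.05. The list passed limma's camera test with an adjusted p of 9.04e-15, and adjusted p = 0.30 with an estimated correlation of 0.38 between its genes. The mean list score was 0.34 ± 0.45 (SD, n = 4) in controls and −0.34 ± 0.16 (SD, n = 4) in pea fiber pigs, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows. With permutation within slides only, the exact p was 0.0556, the smallest that these permutations allow. Control 5 had the highest score, 0.99, and without it the difference in score was −0.46 ± 0.12 (SE). Leaving out the most extreme pig narrows this SE. The difference was −1.01 among the pigs of slide 1 and −0.34 among those of slide 2.

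**Figure D1:**
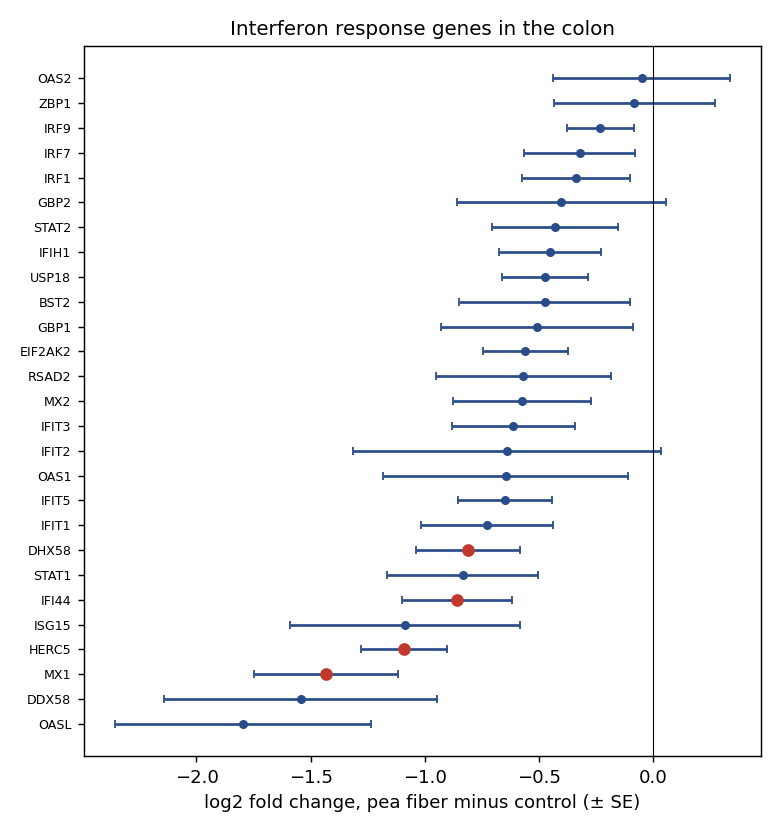
Log2 fold change, pea fiber minus control, of the 27 tested interferon response genes on the horizontal axis, with bars of 1 standard error from limma; red points are the 4 genes that passed adjusted over the list alone. All 27 points lie below 0, from −0.05 for OAS2 to −1.80 for OASL.

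Genes of antigen presentation and of inflammatory signalling had lower means in pea fiber pigs as well, and 0 of them passed limma's test over all genes or adjusted over the list alone. With the slide as a block IL27 passed over the list alone with a limma adjusted p of 0.0322, as did NR4A3 of the stress genes with 0.0184. All 24 antigen presentation genes had a lower mean in pea fiber pigs, with an average difference of −0.42. Among them were PSMB8, an immunoproteasome subunit (−1.13 ± 0.34 SE), TAP2, a peptide transporter (−0.42 ± 0.16 SE, with 4 probes from −0.47 to −0.08), PSMB9 (−0.53 ± 0.24 SE) and SLA-DMA (−0.39 ± 0.17 SE). Of 33 proinflammatory cytokine and NF-kB genes, 29 were lower and 4 higher, with a mean of −0.40. They were led by the chemokines CXCL9 (−1.47 ± 0.42 SE), CXCL10 (−1.57 ± 0.50 SE) and CXCL11 (−1.50 ± 0.62 SE), which interferon induces and which attract T cells, and by PTGS2 (−0.89 ± 0.41 SE). On slide 2 the diets overlapped in PTGS2 and in CXCL11, which was at −2.16 and −0.47 in controls and −1.16 and −1.55 in pea fiber pigs. CXCL9 and CXCL10 were lower in every pea fiber pig there, with CXCL10 at 3.60 and 3.83 in controls and 3.28 and 3.25 in pea fiber pigs. Of 11 genes of anti-inflammatory signalling and regulatory T cells, 10 were lower. IL27 was at −0.61 ± 0.20 (SE), IL10 at −0.42 ± 0.15 (SE), SOCS3 at −0.68 ± 0.30 (SE) and TGFBR1 at −0.26 ± 0.16 (SE). Of 23 stress and immediate early genes, 18 were lower. NR4A3 was at −1.06 ± 0.31 (SE), HSPA5 at −0.51 ± 0.18 (SE), HSP70.2 at −0.35 ± 0.17 (SE) and DNAJB1 at −0.29 ± 0.15 (SE). In camera the adjusted p was 3.39e-07 for antigen presentation, 0.000126 for proinflammatory genes, 0.00433 for anti-inflammatory genes and 0.00714 for stress genes. In that order these lists had adjusted p = 0.34, adjusted p = 0.34, adjusted p = 0.26 and adjusted p = 0.26 with an estimated correlation in limma's camera. The exact permutation p of the list score was 0.0571 for antigen presentation and for proinflammatory genes and 0.0286 for the anti-inflammatory and stress lists. Within slides the exact p was 0.111 for proinflammatory genes and 0.0556 for the other 3. Over the 28 lists the smallest adjusted exact p was 0.267. With a floor of 0.0286 for each list, a pass after adjustment would need many lists at the floor together. The proinflammatory difference was −0.70 on slide 1 and −0.10 on slide 2, and on slide 2 alone camera gave an adjusted p of 0.687. The anti-inflammatory difference was −0.41 and −0.15, that of antigen presentation −0.50 and −0.34, and that of stress genes −0.24 and −0.20 on slides 1 and 2. On slide 2 alone the camera adjusted p was 0.244 for the anti-inflammatory list and 0.24 for antigen presentation, and for the stress list it was 0.0509 on slide 1 and 0.0565 on slide 2. Without pea fiber 6 the camera adjusted p was 0.0851 for the anti-inflammatory and the stress list, and without control 7 it was 0.0636 for the stress list.

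Lists of markers of the immune cells themselves did not pass camera. The 24 T cell and natural killer cell genes had a mean of −0.13, with 15 lower and 9 higher. CCR7 was at −0.70 ± 0.48 (SE) and GZMA at −0.55 ± 0.38 (SE). The 18 macrophage, dendritic cell and granulocyte genes had a mean of −0.08. The list held VSIG4, a complement receptor of resident macrophages, at 0.74 ± 0.27 (SE) and CXCR2 at −0.32 ± 0.20 (SE). The 15 genes of B cells, plasma cells and immunoglobulin A had a mean of −0.25. The list held TNFSF13B, the B cell survival factor BAFF, at −0.85 ± 0.25 (SE), CCL28 at −0.59 ± 0.35 (SE) and PIGR, which carries immunoglobulin A across the epithelium, at −0.23 ± 0.15 (SE). In limma's camera these lists had adjusted p-values of 0.641, 0.763 and 0.185. The T cell list passed, on the lower side, at 0.000942 without control 3 and 0.00324 without pea fiber 8, and so did the B cell list at 0.0136 without control 5, 0.0326 without pea fiber 8 and 0.026 on slide 2 alone. Of antimicrobial defence, 15 of 21 genes were lower, with DMBT1 at −0.50 ± 0.20 (SE) and CFB at −0.60 ± 0.38 (SE), and a camera adjusted p of 0.211, which was 0.00357 without pea fiber 4 and 0.00596 on slide 2 alone.

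Cell division and metabolic genes formed a further set with lower means in pea fiber pigs. Of 18 proliferation genes, 17 were lower, with a mean of −0.41. TOP2A, a topoisomerase of dividing cells, was at 1.56 ± 0.23 (SD, n = 4) in controls and 0.85 ± 0.35 (SD, n = 4) in pea fiber pigs, a difference of −0.71 ± 0.20 (SE). CCNB1 differed by −0.57 ± 0.22 (SE), CDK1 by −0.53 ± 0.21 (SE) and CENPF by −0.43 ± 0.18 (SE). Of these genes 0 passed over all genes or adjusted over the list alone. With the slide as a block 7 passed over the list alone, TOP2A with a limma adjusted p of 0.0129, CCNB1, CDK1 and, named after their values were seen, AURKA, PCNA, CCNB2 and KIF20A with up to 0.0487. Of 24 genes of cholesterol and lipid synthesis, 21 were lower, with a mean of −0.45. They include the sterol enzymes NSDHL (−0.72 ± 0.30 SE), MSMO1 (−0.85 ± 0.37 SE), SC5D (−0.56 ± 0.28 SE) and CYP51 (−0.62 ± 0.34 SE). Without control 3 NSDHL was at −0.40, MSMO1 at −0.51 and CYP51 at −0.37. Of 23 nuclear genes of oxidative phosphorylation, 22 were lower by small amounts, with a mean of −0.18. NDUFB6 was at −0.32 ± 0.15 (SE), ATP5O at −0.28 ± 0.13 (SE), NDUFC1 at −0.30 ± 0.17 (SE) and COX7A2 at −0.26 ± 0.16 (SE). Of 21 genes of glycolysis and glucose transport, 16 were lower. PGK1 was at −0.50 ± 0.17 (SE), PGAM1 at −0.41 ± 0.24 (SE), GPI at −0.23 ± 0.13 (SE) and FBP1 at −0.27 ± 0.16 (SE). Camera's adjusted p was 6.61e-08 for proliferation, 0.00015 for cholesterol and lipid synthesis, 0.00034 for oxidative phosphorylation and 0.047 for glycolysis. With an estimated correlation limma's camera gave adjusted p = 0.34 for proliferation, adjusted p = 0.59 for cholesterol synthesis and for oxidative phosphorylation, and adjusted p = 0.62 for glycolysis. The exact permutation p of the list score was 0.0571 for proliferation, 0.229 for cholesterol synthesis, 0.257 for oxidative phosphorylation and 0.514 for glycolysis, and within slides it was 0.0556, 0.0556, 0.111 and 0.333. The proliferation difference was −0.31 on slide 1 and −0.50 on slide 2, that of cholesterol synthesis −0.49 and −0.40, that of oxidative phosphorylation −0.13 and −0.23, and that of glycolysis −0.08 and −0.15. The camera adjusted p for cholesterol synthesis was 0.0561 without control 3. For oxidative phosphorylation it was 0.0588 without pea fiber 8 and 0.055 on slide 1 alone. The glycolysis call was lost under 14 of 26 alternatives, with adjusted p-values of up to 0.652 with fry and of 0.421 on slide 1 alone.

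Markers of the muscle and nerve layers were higher in pea fiber pigs on average. Of 16 smooth muscle genes, 13 were higher, with a mean of 0.34. They include FLNA (0.57 ± 0.41 SE), CNN1 (0.50 ± 0.38 SE), PLN (0.44 ± 0.35 SE) and KCNMB1 (0.41 ± 0.29 SE). Without pea fiber 4 FLNA was at 0.19 and KCNMB1 at 0.15, and without control 3 CNN1 was at 0.21 and PLN at 0.16. Of 13 genes of enteric neurons and glia, 11 were higher, with a mean of 0.22. They include STMN2, a growth-associated protein of neurons (0.57 ± 0.25 SE, 12 of 12 probes higher), and RET, the receptor that enteric neurons need to develop (0.39 ± 0.17 SE), with NPY at −0.81 ± 0.38 (SE). Camera's adjusted p was 0.00021 for smooth muscle and 0.00218 for neurons and glia, with adjusted p = 0.59 and adjusted p = 0.44 with an estimated correlation. Their exact permutation p was 0.343 and 0.286, and within slides 0.444 and 0.167. The smooth muscle difference was 0.91 on slide 1 and −0.22 on slide 2, where CNN1 was at −0.093. Camera's adjusted p for the list was 0.141 without control 3 and 0.101 without pea fiber 4. The score difference for neurons and glia was 0.37 on slide 1 and 0.075 on slide 2. For this list the camera adjusted p was 0.296 without control 3, 0.0664 on slide 2 alone and 0.0612 for probes well above background on all 8 arrays. The 17 epithelial genes had a mean of −0.05, with KRT20 at −0.32 ± 0.22 (SE) and LGALS4 at −0.21 ± 0.15 (SE). The 16 endothelial genes had a mean of −0.00, with VWF at 0.33 ± 0.18 (SE) and PROX1 at −0.20 ± 0.17 (SE). Of 15 adipocyte genes, 13 were higher, with a mean of 0.09. LIPE was at 0.42 ± 0.31 (SE), and in contrast RETN, the hormone resistin, was at −1.48 ± 0.60 (SE), with 3 of 4 pigs of each diet well above background. The 32 genes of extracellular matrix and fibroblasts had a mean of −0.07. The list held MMP12, a macrophage elastase, at −2.17 ± 0.92 (SE), above background in 3 of 4 pea fiber pigs and at −1.33 without pea fiber 10, and TIMP3 at 0.32 ± 0.17 (SE). In limma's camera these 4 lists had adjusted p-values of 0.509, 0.145, 0.132 and 0.185. Some passed on the higher side under an alternative: the endothelial list at 0.0124 without control 5, the adipocyte list at 0.0142 without control 3, 0.028 without pea fiber 10 and 0.0293 for probes well above background on all 8 arrays, and the matrix list at 0.028 without pea fiber 10, 0.031 with normexp and 0.00154 on slide 1 alone.

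**Figure D2:**
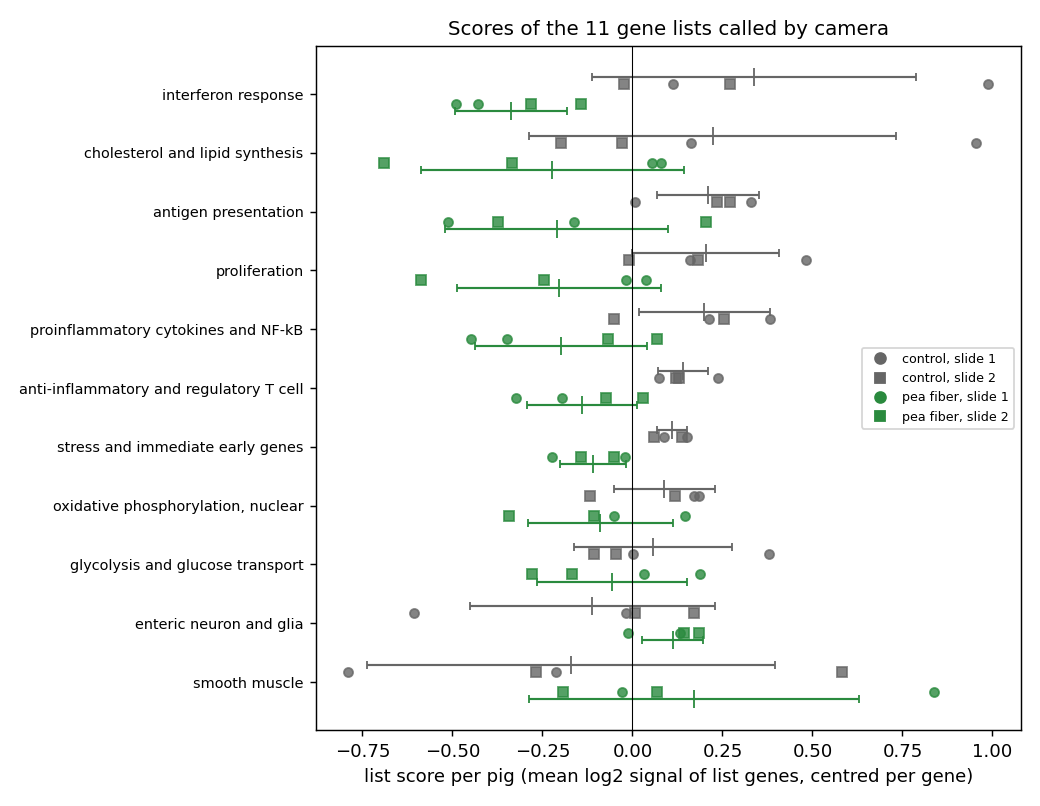
Score of each gene list that passed camera, per pig (mean log2 signal of the list's genes after each gene was centred over the 8 pigs), with grey for control, green for pea fiber, circles for slide 1 and squares for slide 2; bars are means with 1 SD of 4 pigs. Interferon response scores run from −0.49 to −0.14 in pea fiber pigs and from −0.02 to 0.99 in controls.

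The lists of barrier, mucus and fermentation genes did not pass camera. OCLN, a tight junction protein, was at 2.23 ± 0.12 (SD, n = 4) in controls and 2.34 ± 0.08 (SD, n = 4) in pea fiber pigs, a difference of 0.11 ± 0.12 (SE). MUC2, the main mucin of the colon, differed by 0.015 ± 0.50 (SE), and under median centring it stood at −0.003. Of 21 tight junction and adhesion genes, 12 were higher and 9 lower. CLDN8, a sealing claudin, was at −1.63 ± 0.72 (SE) and JAM3 at 0.49 ± 0.26 (SE). Of 13 mucin and goblet cell genes, 7 were higher and 6 lower. TFF1 was at −1.26 ± 0.60 (SE), above background in 2 of 4 pea fiber pigs and at −0.69 without control 5. C1GALT1C1 was at −0.35 ± 0.20 (SE), and at −0.20 without pea fiber 10. The list's median of 0.01 and mean of −0.14 differ in sign. Of 11 genes of short-chain fatty acid transport and sensing, 8 were higher, with a mean of 0.21. ABCG2, an efflux pump of the colonocyte surface, differed by 1.26 ± 0.41 (SE, 4 of 4 probes higher), ACSS2 by −0.40 ± 0.38 (SE) and SLC16A1, the monocarboxylate transporter that takes up butyrate, by 0.17 ± 0.42 (SE). Of 31 genes of fatty acid oxidation and ketogenesis, 16 were higher and 15 lower. PDK4, a kinase that turns cells from glucose to fat oxidation, was at 1.26 ± 0.46 (SE, 9 of 9 probes higher). ECHS1 was at −0.59 ± 0.24 (SE), with its other probe at −0.08. Of 23 genes of colonocyte ion and water transport, 15 were higher, with GUCA2B, the gut peptide uroguanylin, at 0.55 ± 0.35 (SE) and KCNQ1 at −0.39 ± 0.25 (SE). Camera's adjusted p in limma was 0.34 for tight junctions, 0.536 for mucins, 0.0534 for short-chain fatty acid genes, 0.424 for fatty acid oxidation and 0.185 for ion transport. The short-chain fatty acid list passed, on the higher side, at 0.00665 without pea fiber 4, 0.0072 without pea fiber 8, 0.0142 without control 9 and 0.0268 on slide 1 alone, and the ion transport list at 0.0128 without pea fiber 8. Among immune genes fixed in advance, besides IL10 and PIGR given above, TNF differed by 0.00 ± 0.21 (SE), IL6 by −0.56 ± 0.38 (SE) and TLR4, a receptor for bacterial lipopolysaccharide, by −0.14 ± 0.22 (SE), and TNF took a value above 0 (0.01) under quantile normalization and in the authors' table. A second TNF probe was at 0.30. TFF3 and TJP1 were not named on the array as annotated here, and CLDN1 and FFAR2 were too dim to pass the filter.

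Among the other lists, CHGB, a granin of enteroendocrine cells, was at 2.26 ± 0.07 (SD, n = 4) in controls and 1.45 ± 0.40 (SD, n = 4) in pea fiber pigs, a difference of −0.81 ± 0.20 (SE). In all, 15 of 15 probes were lower. It was the 1 enteroendocrine gene of 13 that passed adjusted over the list alone, with a limma adjusted p of 0.0377, and 0 passed over all genes. Over the list alone CHGB was at 0.0708 to 0.127 without any 1 pig other than pea fiber 6, at 0.0553 with the slide as a block and at 0.0532 with quantile normalization. SCG5 was at 0.45 ± 0.25 (SE). In Wnt and crypt stem cell genes 7 were higher and 7 lower, with ASCL2 at −0.27 ± 0.20 (SE) and BMI1 at 0.47 ± 0.35 (SE). ASCL2 was at −0.14 without control 3, and BMI1 was at 0.10 without pea fiber 4. In apoptosis 14 of 21 genes were lower, with PMAIP1 at 0.52 ± 0.23 (SE). Among 24 xenobiotic genes 14 were lower, with GSTA1 at −1.94 ± 1.19 (SE) and HMOX1 at 0.63 ± 0.43 (SE), which were at −1.03 and 0.24 without pea fiber 8. The 4 lists had adjusted p-values of 0.679, 0.584, 0.241 and 0.65 in limma's camera. Camera, which compares a list with all other genes, put the Wnt, xenobiotic, matrix and endothelial lists on the higher side although their means were −0.01, −0.04, −0.07 and −0.00.

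The single genes with the smallest unadjusted p on each side, none of which passed the adjusted threshold, were of mixed function. On the higher side they were CLDN10, a claudin that forms ion pores (1.26 ± 0.23 SE), LOC396867, annotated as stefin A8 (0.93 ± 0.20 SE), CDHR1 (0.75 ± 0.17 SE), SCD5, a stearoyl-CoA desaturase (0.53 ± 0.13 SE), CHST15 (0.62 ± 0.16 SE), ABCA6 (0.77 ± 0.21 SE), DDO (0.80 ± 0.22 SE), KLF11 (0.84 ± 0.26 SE), SAG (0.61 ± 0.19 SE, 2 of 3 probes higher and another at −0.52) and TNNC1, a troponin of slow muscle (1.55 ± 0.48 SE, above background in 3 of 4 controls). On the lower side, besides HERC5, MX1 and CHGB, they were CYP2C42, a cytochrome P450 (−1.66 ± 0.32 SE), LOC100155366 (−0.69 ± 0.14 SE), LOC100156248 (−0.67 ± 0.15 SE), FAM136A (−0.61 ± 0.14 SE), DCSTAMP (−0.62 ± 0.15 SE), GSR, glutathione reductase (−0.49 ± 0.12 SE), and ARG2, a mitochondrial arginase (−0.81 ± 0.20 SE).

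Over all 30282 tested probes, limma called 0 different between the diets at an adjusted p under 0.05. A test of each probe with separate variances for the diets also called 0. At an unadjusted limma p under 0.05 there were 965 probes, 381 higher and 584 lower in pea fiber pigs. A share of 0.05 of the tested probes is 1514. This fit leaves the slide differences in the residual spread, so 1514 is not its chance level. Other splits of the pigs that were balanced over the slides gave 409 to 1730 probes. With the slide as a block the count was 1776, 606 higher and 1170 lower, and limma again called 0, with a smallest adjusted p of 0.389. An unadjusted p under 0.05 with at least a 2-fold difference held for 119 probes, 55 higher and 64 lower, and 61 of them carried symbols of 42 genes. The diets did not overlap in 693 probes, or 2.29%, where chance without slide differences gives 2.86%. With 1 pig left out the difference of 44 of 100 named genes moved by over 1.5 times or changed sign, for 20 of them without control 3, 14 without pea fiber 8 and 13 without pea fiber 4. Of the 551 tested genes in any list 0 passed over all genes in limma, and 41 had an unadjusted p under 0.05, 6 higher and 35 lower. In all, 11 of 28 lists passed camera with the preset correlation, 9 lower and 2 higher, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and 0 passed fry in its directional or mixed form. The stress list came closest, with an adjusted p of 0.0542 in directional fry. How often the estimated correlation or fry would find a true shift was not simulated, so their 0 calls do not show that no list differs.

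The slide separated the samples more than the diet. Each slide held 2 pigs of each diet, and the first principal component, with 37.3% of the variance, parted the slides. In limma 3302 probes differed between slides with adjusted p under 0.05, 2218 higher and 1084 lower on slide 2. The Y-linked gene UTY was well above background in 2 of 4 control pigs and 3 of 4 pea fiber pigs, and the labels used here do not give the sex of the pigs. With the UTY level as a covariate, an alternative chosen after seeing the data, limma called 0 probes, with 825 at an unadjusted p under 0.05, and camera called 10 lists.

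**Figure D3:**
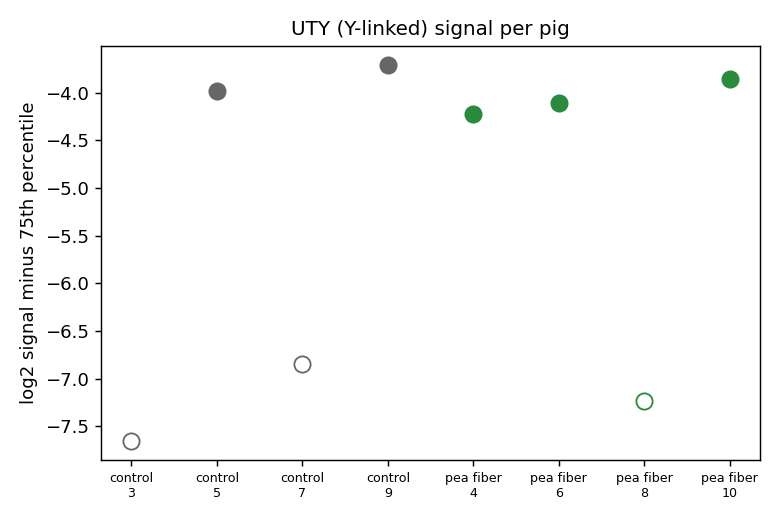
Log2 signal of the UTY probe per pig, relative to each array's 75th percentile, with grey for control and green for pea fiber; filled points were well above background and open points were not. The 5 filled points lie between −4.22 and −3.71 and the 3 open points between −7.65 and −6.85.

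**Figure D4:**
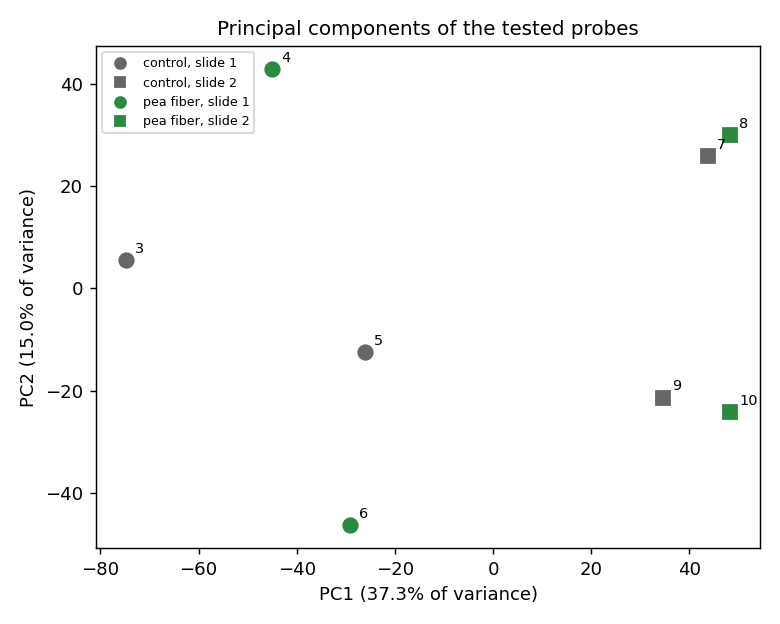
First and second principal components of the tested probes, one point per pig with its label number, the first with 37.3% of the variance; grey is control, green is pea fiber, circles are slide 1 and squares slide 2. The slides lie on opposite sides of 0 on the first component, and the diets overlap on both.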

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

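Of 256 groups of 4 pigs examined, over 100 named genes and 28 list scores, 10 held 1 pig far from the other 3 of its diet, 3.9%, where chance gives about 1 in 20. Pea fiber 4 had the highest CLDN8 of its diet, −0.12 against −3.19 to −2.71 in the others, the lowest GZMA, −0.55 against 0.48 to 0.63, and the lowest score of fatty acid oxidation genes, −0.077 against 0.05 to 0.06. Pea fiber 6 had the highest ABCG2, 4.84 against 3.99 to 4.09, and pea fiber 10 the highest DCSTAMP, −3.99 against −4.35 to −4.29. Control 3 had the lowest PDK4, −0.42 against 0.32 to 0.41, the lowest PMAIP1, −1.39 against −0.66 to −0.56, and the highest OCLN, 2.41 against 2.16 to 2.18. Control 7 had the lowest CXCL11, −2.16 against −0.47 to −0.34, and the lowest GSTA1, −1.03 against 2.02 to 2.41.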

How the results depend on the processing

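The alternatives with UTY as a covariate, with the slide block and an estimated correlation together, and with exact permutation of list scores were chosen after seeing the data. In limma 0 probes and 0 list members passed over all genes under every alternative run, Welch's test and the 0.10 threshold included, with 965 probes at an unadjusted p under 0.05 as reported and 750 to 1776 under the alternatives that tested 8 or 7 pigs with the same filter. The list count of 11 was 0 with an estimated correlation, with fry, with mixed fry, with the slide block and an estimated correlation, and by exact permutation, 7 on slide 2 alone, and 9 to 13 when 1 pig was left out. The exact permutation p cannot fall below 0.0286 here. Many of the 28 lists would have to reach that floor together for any to pass after adjustment. The 0 by exact permutation was thus largely fixed by the design and says little about the lists. In the simulation with no effect and the correlations estimated here, camera called 5.76 lists with the preset correlation and 0 with an estimated one. For lists with a high estimated correlation, such as the interferon list at 0.38, the preset calls thus rest on taking their genes as nearly independent. For the anti-inflammatory and stress lists the estimated correlation was 0.011 and −0.022, near or below the preset of 0.01. Correlation therefore does not account for the loss of their calls. The cause of the other changes was not tested. The count of list members past the threshold over the list alone, 5, was 2 with quantile normalization, the authors' table, no filter or slide 2 alone, 3 with array weights, 8 with the filter on all 8 arrays, with trend and robust or with UTY as covariate, 11 with UTY and the slide block, 13 with the slide block, and 2 to 7 with 1 pig left out. The count of 119 probes with 2-fold and unadjusted p was 18 with normexp and quantile normalization of the median signal, 234 with no filter, 363 on slide 1, 280 on slide 2, 437 at 1.5-fold, 54 with Welch's test, and 115 to 203 with 1 pig left out (203 without control 7, 179 without pea fiber 4). The normexp setting adds 50 to signals whose array median was 37.65 to 50.4, which narrows the log2 differences of dim probes. With it HERC5 was at −0.58 instead of −1.09 and IFI44 at −0.36 instead of −0.86, while the brighter MX1 was at −1.30 instead of −1.43. The cause of the other changes was not tested.

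Of the 11 called lists the interferon and proliferation lists lost their call only with an estimated correlation (with or without the slide block), fry and exact permutation, among the alternatives run. Exact permutation could hardly have kept any call, given its floor. The smooth muscle list turned lower on slide 2 (camera adjusted p 0.265). Lists with no call that changed side were, on slide 2, T cells (0.705), Wnt (0.705), apoptosis (0.831), ion transport (0.894), enteroendocrine (0.705) and matrix (0.153), on slide 1 the epithelial list (0.843), with fry the Wnt (0.99) and xenobiotic lists (0.853), and the enteroendocrine list with array weights (0.836), UTY (0.959) and UTY with the slide block (0.834). With 1 pig left out their adjusted p ran from 0.326 to 0.952 for mucins, 0.000942 to 0.794 for T cells (higher without control 7, control 9, pea fiber 4 or pea fiber 6, lower in the other 4), 0.101 to 0.948 for macrophages, 0.287 to 0.952 for Wnt, 0.34 to 0.952 for xenobiotic genes, 0.346 to 0.919 for enteroendocrine, 0.028 to 0.736 for matrix and 0.0851 to 0.842 for epithelial genes. The short-chain fatty acid list, at 0.0534 as reported, came to 0.05 with median centring, 0.0467 with the filter on all 8 arrays and 0.023 with the mean of all probes, and ran from 0.00665 to 0.406 with 1 pig left out. Of the other lists with no call, 1 pig left out took the lowest adjusted p to 0.00357 for antimicrobial, 0.0124 for endothelial, 0.0128 for ion transport, 0.0136 for B cell and 0.0142 for adipocyte genes.

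Of 100 named genes, 94 kept their sign under all alternatives run and 0 passed. Most of them were named for a small p in these same pigs, so a kept sign is little support. MUC2, TNF and SLC16A1, which were fixed in advance, changed sign. On slide 2 TFF1 was at 0.15, GUCA2B at −0.086, CNN1 at −0.093 and TNF at 0.092. MUC2 was at −0.003 with median centring, −0.037 on slide 1 and 0.00 with UTY. TNF was at 0.004 with normexp, 0.01 with quantile normalization and in the authors' table, 0.019 with array weights, 0.026 with UTY and 0.014 with UTY and the slide block. With 1 pig left out MUC2 ran from −0.28 to 0.34, TNF from −0.17 to 0.10 and SLC16A1 from −0.045 to 0.57; the cause was not tested. Probes well above background on fewer than 4 of the 8 arrays, among them those for CLDN1 and FFAR2, were tested only in the fit with no filter.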

Other observations

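The tests named here with control 5 left out, with immune cell or epithelial scores subtracted, with UTY, immune cell or smooth muscle scores as a covariate and with the UTY split were chosen after the result was seen. Among the 119 probes with at least a 2-fold difference at an unadjusted limma p under 0.05 were further genes, chosen after their values were seen, none of which passed the adjusted threshold. TNNT1, a troponin of slow muscle, was at 1.02 in a probe above background in 2 of 4 controls, at 1.05 in another and at 0.26 in its brightest probe, which had an unadjusted limma p of 0.401. CYP2B22, a cytochrome P450, was at 1.90 in a probe well above background in 1 of 4 controls, and its brightest probe was at 1.64 with an unadjusted limma p of 0.0724. SULT2A1, a sulfotransferase of steroids and bile acids, was at −1.47, above background in 2 of 4 pea fiber pigs. Of interferon response genes, OASL was at −1.80, DDX58, the RNA sensor RIG-I, at −1.54 and −1.49 in 2 probes, above background in 2 and 3 of 4 pea fiber pigs, and RSAD2, an antiviral enzyme, at −1.18 in 1 probe and −0.57 in its brightest, with an unadjusted limma p of 0.174. ACOD1, which makes itaconate in activated macrophages, was at −1.57 and −1.16 in 2 probes, both above background in 1 of 4 pea fiber pigs, so that these sizes lie near the floor. SPP1, osteopontin, was at 1.06, with 4 of 4 probes higher.

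The counts were set against other splits of the same 8 pigs. The 0 probes of the diet split cannot be tested in this way, since all 35 of 35 splits have at least 0; the highest count, 3562, was in the split that follows the slides, which points to the slide as the main structure of the samples. Chance cannot be excluded for the next 3 counts. At least 119 probes passed the 2-fold rule in 25 of 35 splits, with 1345 as the highest other, again in the slide split; within slides the rule gave 363 and 280. Camera called at least 11 lists in 5 of 35 splits, with 12 as the highest other, none of them the slide split. At least 5 list members passed over the list alone in 7 of 35 splits, with 55 as the highest other, in the slide split. Many of the 35 splits are not balanced over the slides and carry the slide difference, unlike the diet split. These shares are therefore no fair measure of chance. Among the 18 balanced splits the highest other was 224 probes by the 2-fold rule, 12 lists and 8 list members. The blocked fit was compared over the 18 splits balanced over the slides, too few for a share under 0.05. Of these, 6 had at least the 1776 probes at an unadjusted p under 0.05 with 2889 as the highest other, 4 had at least the 11 lists, with 12 as the highest other, and 1, the diet split itself, had at least the 13 list members past the threshold over the list alone, with 7 as the highest other.

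The lower interferon genes of pea fiber pigs were weighed against 3 explanations. A single control pig with high interferon genes is argued against as the whole cause, since the score difference without control 5 was −0.46 ± 0.12 (SE) against −0.67 ± 0.24 (SE) with it. Control 5 was picked as the pig with the highest score, which narrows the SE without it, so that SE is no fair error. The other controls, from −0.02 to 0.27, still scored above every pea fiber pig, the highest of which was at −0.14. An uneven sex of the pigs, read from UTY, is argued against as the whole cause too, since the diet difference was −0.70 ± 0.26 (SE) with the UTY level as a covariate. Fewer T cells and macrophages stay open, since 1 of 2 tests goes against them: with the mean of both cell scores as a covariate the difference was −0.66 ± 0.26 (SE), while the interferon score minus that mean differed by −0.57 ± 0.31 (SE; exact permutation p 0.171), too wide to decide with 4 pigs per diet. A hypothesis that stays open is that pea fiber may lower the interferon tone of the colon, next to chance and a difference between pens or in infection that the labels do not record.

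The lower proliferation genes came with higher smooth muscle genes on average, so that a thicker share of muscle in the pea fiber samples could dilute the crypts, and with them all epithelial genes alike. The proliferation score minus the epithelial score differed by −0.35 ± 0.13 (SE; exact permutation p 0.0571), only just beyond the bound set for it after the smooth muscle covariate had left the question undecided, with a proliferation difference of −0.38 ± 0.20 (SE) against −0.41 ± 0.18 (SE) without it. More muscle therefore cannot be told apart from a lower proliferation with 4 pigs per diet, although on slide 2 proliferation was at −0.50 where smooth muscle was at −0.22. With UTY as a covariate it was −0.43 ± 0.19 (SE), which argues against sex as the whole cause. Slower turnover of the epithelium and a smaller share of crypts in the pieces taken are hypotheses that no test here separates, and chance stays open too.

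Some probes were bright in some pigs and near background in others. UTY stood at −3.98 in control 5, −3.71 in control 9, −4.22 in pea fiber 4, −4.11 in pea fiber 6 and −3.86 in pea fiber 10, and was not well above background in control 3, control 7 and pea fiber 8. The probe of SRY, also Y-linked, was not well above background in any of the 8 pigs, with values from −7.65 to −6.85, and so did not part them. Besides UTY, 14 probes parted the same 3 samples from the other 5 by at least 4-fold, 9 of them higher in the 5, among them a probe annotated to KDM6A, the X-linked relative of UTY, and one whose description names a zinc finger X-chromosomal protein. Of the 56 splits into 3 and 5 samples, 1, the split by UTY itself, parted as many probes, and the highest of the others parted 5. A candidate explanation is that both sexes are present, with the KDM6A and zinc finger probes perhaps reading Y-linked copies, which was not tested; SRY gives no evidence for it. The place of the unnamed probes in the genome was not tested.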
